A study of Mus musculus with 22 samples.

How the data were processed

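Single nuclei of the mouse substantia nigra pars reticulata (SNr) were profiled by RNA sequencing after retrograde labelling from 6 targets, per the labels. A retrograde AAV carrying a nuclear mCherry under the hSyn promoter was injected into these targets, and labelled nuclei were sorted singly into 96-well plates with DAPI as the nuclear stain, per the labels' protocols. The targets are given as LSC, MSC, IC, DR, PNo and Med, with 4, 2, 3, 5, 4 and 4 plates (22 in all). Tissue of 3 to 4 mice was pooled for a preparation, per the labels' protocols, and nothing in the labels ties a plate to a pool. The spread between plates of 1 target may therefore be partly technical, and a target cannot be separated from the preparations made for it. Plates are named here by target and the replicate number of the labels.

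The deposited files hold raw counts per gene and well, 1 matrix per plate, with 96 wells each. The values were checked to be whole numbers that differ in sum between wells and plates. Reads were aligned with STAR to mm10, per the submitters' processing notes. The library kit, the use of molecular identifiers or strand, the counting tool, the annotation release and the STAR version are not given in the sources used here. Intervals and floors therefore cover counting error only, and genes that overlap on opposite strands cannot be told apart, which concerned 111 of the 230 genes named by rule. Of 41643 gene names, 40460 matched a reference symbol. Positions are from GENCODE vM21 (GRCm38, the assembly of mm10), found for 228 of those 230 genes. The mCherry transcript was not among the gene names.

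A nucleus was kept with at least 1000 genes detected and at most 5% of counts from the mitochondrial genome. This left 2109 of 2112 wells, and the highest mitochondrial percentage was 0.854%. Counts were scaled to 10000 per nucleus and log transformed in scanpy 1.11.5 (Python 3.11.15). From 2000 variable genes, without mitochondrial and sex-linked ones, 30 principal components and 15 neighbours gave 17 Leiden clusters at resolution 1.0. Clusters that were not GABAergic, or that raised markers of another class, were clustered again, for 33 in all. The GABAergic-like name went to 20 clusters, in which at least 3 of 4 marker genes, Gad1, Gad2 and Slc32a1 among them, were detected in at least 20% of nuclei and Gad1 and Gad2 together reached at least 3 times Slc17a6. Another class was named where at least 3 of its markers were raised at least 2-fold over the other nuclei and 1 of them was among the top 10 genes, and a cluster that met neither rule was left unnamed. The marker lists were fixed in advance. The top 10 rule, its pseudocount of 1.0 and the trigger for clustering again were set after the clusters had been seen. With a pseudocount of 0.05, Th, C1ql1, Vcan, Cldn11 and Slc17a6 entered the top 10 of single clusters. No doublet caller was used, because nuclei were sorted singly.

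Counts were summed per plate over GABAergic-like nuclei (74 to 92 per plate, 1066429 to 2120970 counts). With edgeR 4.0.16 (R 4.3.3), filterByExpr at a minimum count of 10 left 13457 genes, which were scaled by TMM. One quasi-likelihood fit over the 22 plates, with a mean per target and no covariate, gave a common biological coefficient of variation of 0.222. Its tests were an F test over the 6 targets, each target against the equally weighted log2 mean of the other 5, MSC against LSC, and PNo against Med. All were two-sided with Benjamini-Hochberg adjustment at 0.05, and "edgeR adjusted p" below means this. Log2 values are given with their standard error. CPM (counts per 1000000 of a plate's sum over the tested genes, scaled by TMM) are given as mean ± SD over plates. On simulated plates with 200 changed genes among 13013, the LSC comparison recovered 85% of genes changed 4-fold and 63% of those changed 2-fold. Of 153 calls 5 were false (3.27%), and 100% of the changed genes that were tested had the right sign, recovered or not.

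Shares of nuclei with a count were taken for 12 genes fixed in advance, after each GABAergic-like nucleus had been thinned to 7423 counts (the 10th percentile of totals). The 195 nuclei below that total were left out. Shares across targets were compared with a permutation test of their between-target variance (100000 shuffles of plate labels), and each target against all other plates with an exact permutation test of the difference of means (two-sided, adjusted over 72 tests). Shares of nuclei per class were compared across targets in the same way.

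Gene lists fixed in advance (24) were developmental transcription factors, Hox genes, GABA synthesis and transport, calcium-binding proteins, neuropeptides, neuropeptide receptors, monoamine and acetylcholine receptors, potassium channels, a joint list of sodium, calcium and pacemaking channels, ionotropic and metabotropic glutamate receptors, GABA and glycine receptors, axon guidance, adhesion molecules, myelin, astrocyte, microglia, dopamine neuron, glutamate neuron and immediate early genes, interferon response, mitochondrial genome, cytosolic ribosomal proteins and sex-linked genes. Each of the 23 with a tested member was tested in each target comparison (138 tests) with camera of limma 3.58.1, on log2 CPM at a prior count of 2 and a preset correlation of 0.01. The same tests were run with an estimated correlation and with fry.

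Genes are named by a rule fixed in advance. For each target comparison it took the 8 highest and 8 lowest log2 changes past the test with a mean of at least 10 CPM on the higher side and every plate of the target on the same side of the median of the other plates, and for the pairs the 5 highest and lowest. Predicted and clone names were passed over. It also took the 10 smallest p of the F test, up to 4 members past the test per list and target comparison, Gad1, Gad2, Slc32a1, Slc17a6, Th, Slc6a3, Pvalb and the 12 genes of the shares. Results for some of these genes are not reported here. Groups, tests, lists, this rule and the alternatives, except those said to be later, were chosen before the data were examined.

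Alternatives were other scalings (relative log expression, library size alone), no gene filter, other choices of nuclei (all classes, at least 2000 genes, no filter, without very high totals, GABAergic by at least 2 of Gad1, Gad2 and Slc32a1 without Slc6a3 and Slc17a6), nuclei thinned before summing, DESeq2 1.42.0, plate numbers as a block, each plate left out in turn, other thresholds of detection and Leiden resolutions of 0.5 and 2.0. Leaving out 1 MSC plate leaves a lone plate, which is then assumed to vary like the other groups. Alternatives chosen after seeing the data left out GABAergic-like nuclei of clusters 5 and 16 (low totals, metabolic genes leading), of 4 sub-clusters of cluster 10 (numbers 1, 3, 4 and 6, split from a cluster with Slc17a6 nuclei), or of sub-cluster 2.3 (myelin RNA).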

Results

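The series asked whether SNr neurons that project to different targets differ in gene expression. RNA was counted in single nuclei labelled from 6 targets, which the labels name only as LSC, MSC, IC, DR, PNo and Med. LSC, PNo and Med had 384 wells each on 4 plates, MSC 192 wells on 2 plates, IC 288 wells on 3 plates and DR 480 wells on 5 plates. The median well held 17611.5 counts and 4966.5 detected genes. Total counts per plate ran from 1356110 to 2390899. In units of 1000000 counts their mean was 1.96 ± 0.147 in LSC (SD, n = 4), 1.64 ± 0.406 in MSC (n = 2), 1.61 ± 0.109 in IC (n = 3), 1.70 ± 0.273 in DR (n = 5), 1.89 ± 0.388 in PNo (n = 4) and 1.73 ± 0.204 in Med (n = 4). No pair of plates was identical, and plates of the same target differed by more than counting error, with a chi-square per gene of 2.95 to 9.67.

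Most nuclei carried the transcripts of GABA neurons. GABAergic-like nuclei, named for markers that include Gad1 and Gad2 (GABA-synthesising enzymes) and Slc32a1 (the vesicular GABA transporter), were 1882 of 2109. Their share was 92.7 ± 2.82% in LSC (SD, n = 4), 84.9 ± 11.0% in MSC (n = 2), 83.0 ± 3.35% in IC (n = 3), 91.7 ± 4.36% in DR (n = 5), 88.2 ± 4.47% in PNo (n = 4) and 90.6 ± 4.58% in Med (n = 4). Another 208 nuclei met no naming rule, 10 were dopaminergic-like and 9 oligodendrocyte-like. Gad1 was detected in 80.0% of the dopaminergic-like and 77.8% of the oligodendrocyte-like nuclei. These 2 names therefore do not exclude GABA neurons that also held other RNA. Dopaminergic-like nuclei numbered 5 in IC, 3 in PNo and 1 each in LSC and Med, against 0 in MSC and DR, which allows shares of up to 1.56% and 0.625%. Oligodendrocyte-like nuclei numbered 5 in Med, 3 in MSC and 1 in DR, against 0 in LSC, IC and PNo, which allows up to 0.781%, 1.04% and 0.783%. No class differed in share across targets (two-sided permutation test, adjusted p = 0.152 for GABAergic, dopaminergic and oligodendrocyte-like nuclei and 0.257 for unnamed ones). At an unadjusted p the lowest was 0.0636. Shares passed the test without IC replicate 2 (dopaminergic, range across targets 2.60 points, adjusted p = 0.0291), MSC replicate 1 (GABAergic 15.6 and unnamed 15.9, both 0.0322) or MSC replicate 2 (oligodendrocyte-like 3.13, 0.0275), and with other clustering or at least 2000 genes per nucleus.

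Summed per plate over GABAergic-like nuclei, Gad1 ran from 209 ± 24.1 CPM in DR (SD, n = 5) to 290 ± 27.4 in LSC (n = 4), and Gad2 from 246 ± 21.8 in IC (n = 3) to 284 ± 13.8 in DR (n = 5). Slc32a1 ran from 12.8 ± 8.34 CPM in IC to 26.7 ± 9.84 in Med. Slc17a6, a vesicular glutamate transporter, ran from 5.67 ± 3.78 in LSC to 17.6 ± 4.50 in IC. Th and Slc6a3, which mark dopamine neurons, reached at most 8.62 ± 5.35 CPM (PNo) and 8.49 ± 7.35 CPM (IC). None of these 6 genes passed the edgeR test in any target. Their smallest adjusted p were 0.0571 (Slc6a3 in IC, log2 1.88 ± 0.62) and 0.0828 (Gad1 in LSC, log2 0.30 ± 0.11).

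A test across all 6 targets asked which genes differed at all. Adarb2, an RNA-editing family member, was at 5080 ± 742 CPM in LSC (SD, n = 4) and 225 ± 68.3 in DR (n = 5). Kcnma1, the pore of the BK potassium channel, was at 2100 ± 177 CPM in LSC, 1155 ± 43.3 in IC (n = 3) and 450 ± 60.6 in DR, and its partner Kcnmb2 at 600 ± 31.0 in LSC and 64.1 ± 13.8 in DR. The Wnt-pathway transcription factor Tcf7l2 was at 467 ± 54.8 CPM in IC and 16.6 ± 6.25 in DR, while the secreted protein gene Tafa1 was at 1146 ± 155 in DR and 149 ± 24.3 in IC. These 5 genes and Ror1, Sox5, Zfhx3, Fign and Pld5 had the smallest p of the F test (edgeR adjusted p from 4.07e-17 to 5.32e-15). In all, 2068 of 13457 genes (15.4%) passed it. On the first principal component of the 22 plates, with 16.6% of the variance, DR, PNo and Med plates lay between 9.69 and 32.0. LSC, MSC and IC plates lay between -45.2 and -14.5.

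**Figure D1:**
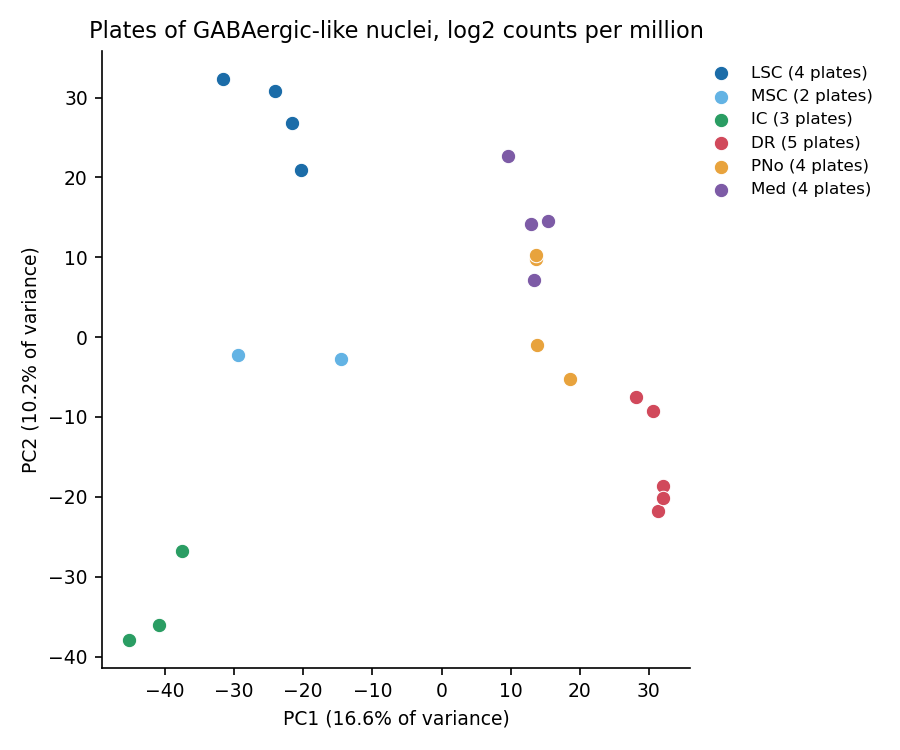
Plates by their position on principal component 1 (16.6% of variance) and 2 (10.2%) of log2 CPM, 1 point per plate, coloured by target. IC plates sit at -45.2 to -37.5 on the horizontal axis and DR plates at 28.2 to 32.0.

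LSC nuclei were compared with the mean of the other 5 targets, and the largest differences included genes of transcription factors, a transporter and channels. The forkhead factor Foxp2 (chromosome 6, 14901349 to 15441977, GRCm38) was at 802 ± 94.4 CPM in LSC (SD, n = 4), 627 ± 254 in MSC (n = 2) and at most 78.6 ± 23.3 in the other targets (log2 3.12 ± 0.19, edgeR adjusted p = 9.53e-14). Ror1, a receptor tyrosine kinase-like protein of Wnt signalling (chromosome 4, 100095791 to 100444765), was at 138 ± 36.9 CPM in LSC and 3.01 ± 1.53 in DR (log2 3.65 ± 0.18, adjusted p = 3.5e-16). Slc38a11, of an amino acid transporter family, reached 25.8 ± 6.18 CPM and was below 1 in IC, DR, PNo and Med (log2 4.29 ± 0.43, adjusted p = 9.28e-09). The homeodomain factor Six3 (chromosome 17, 85613608 to 85629302) was at 50.0 ± 3.57 CPM (log2 3.00 ± 0.26, adjusted p = 2.96e-10). It overlaps Six3os1 (85600651 to 85618398) on the opposite strand, and counts of the pair cannot be told apart. Myzap (log2 3.53 ± 0.38), the homeobox gene Uncx (3.30 ± 0.43), Aoc1, a diamine oxidase (3.09 ± 0.43), and Ano1, a calcium-activated chloride channel (3.02 ± 0.33), completed the 8 highest. Lower in LSC were Fxyd6, a regulator of the sodium pump (log2 -2.15 ± 0.45), the mechanosensitive channel Piezo2 (-1.84 ± 0.37), the dopamine receptor Drd2 (-1.65 ± 0.31) and the cilium gene Hydin (-1.61 ± 0.30). Drd2 was at 5.75 ± 2.86 CPM in LSC and 29.3 ± 7.74 in PNo (n = 4).

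In LSC 896 genes passed the test (604 higher, 292 lower), 272 of them beyond 2-fold. With library size as the scaling the split was 402 higher and 450 lower. Without LSC replicate 3 the count was 589. The remaining 4 of the 8 lowest missed the test under some alternatives. Rpusd3 (-1.73 ± 0.44) missed the test without LSC replicate 2 (-1.41, edgeR adjusted p = 0.0773) and with thinned nuclei (-1.11, 0.243). Baiap3 (-1.58 ± 0.43) missed it without LSC replicate 2 (0.0839), 3 (0.0761) or 4 (0.103) and was at -2.47 without replicate 1. Rsph9 (-1.65 ± 0.48) missed it without LSC replicate 2 (0.159) or 3 (0.122), without MSC replicate 1 (0.0579), with thinned nuclei (-1.57, 0.155) and without 4 sub-clusters of cluster 10 (0.0507), and Arxes1 (-1.61 ± 0.39) with thinned nuclei (-1.44, 0.0825).

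More axon guidance genes were higher than lower in LSC. Of 54 tested, 19 were higher and 3 lower, and 32 did not pass (22 and 7 adjusted over the list alone). Sema3e was higher by 1.64 ± 0.14 on the log2 scale, Sema3c by 1.46 ± 0.16, Rgma by 1.30 ± 0.22 and the semaphorin receptor Nrp1 by 1.24 ± 0.11. The list ranked above the other genes (camera adjusted p = 0.000877), but not with an estimated correlation (adjusted p = 0.0791 with an estimated correlation). Of 43 sodium, calcium and pacemaking channel genes, 12 were higher and 4 lower (20 and 4 adjusted over the list alone), among them the T-type calcium channel Cacna1h (1.88 ± 0.19), Trpc4 (1.65 ± 0.12) and Scn3b (-1.39 ± 0.21). Camera gave an adjusted p = 0.00347, and 0.165 with an estimated correlation. The counts were 7 and 2 without LSC replicate 2 and 6 and 4 without LSC replicate 3. Of 6 metabotropic glutamate receptors 3 were higher and 0 lower (4 and 0 adjusted over the list alone), with Grm3 at 0.64 ± 0.11. The camera adjusted p was 0.0115, then 0.271 with an estimated correlation and 0.0864 with thinned nuclei.

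Of 65 developmental transcription factors, 16 were higher and 3 lower in LSC (18 and 3 adjusted over the list alone), and 46 did not pass. Onecut2 (2.17 ± 0.28) was higher along with Foxp2 and Six3. The camera call (adjusted p = 0.0437, and adjusted p = 0.0791 with an estimated correlation) ended without LSC replicate 1 (0.0669), 3 (0.093, with 11 higher and 3 lower) or 4 (0.0949), IC replicate 1 (0.0635) or 3 (0.0519), PNo replicate 2 (0.0543), 3 (0.0518) or 4 (0.0617), DR replicate 1 (0.0519) or MSC replicate 2 (0.0523), and without LSC replicate 2 the counts were 11 and 1. Of 20 neuropeptide receptors 5 were lower and 1 higher (the same adjusted over the list alone), with the orexin receptor Hcrtr1 at -2.29 ± 0.52. Their camera adjusted p was 0.0115 (0.0791 with an estimated correlation, 0.0935 with nuclei chosen by genes), and 2, 3 and 3 were lower without LSC replicates 1, 3 and 4 and 3 with thinned nuclei. Of 9 neuropeptides 0 passed in edgeR, 2 at an unadjusted p under 0.05 and 0 in DESeq2. The camera call of that list (adjusted p = 0.0484, or adjusted p = 0.320 with an estimated correlation) ended without LSC replicate 2 (0.0658), 3 (0.0655) or 4 (0.135), IC replicate 1 (0.0746) or 2 (0.0601), PNo replicate 1 (0.066), DR replicate 1 (0.0567), 2 (0.0567) or 5 (0.0563), Med replicate 2 (0.0536), 3 (0.0541) or 4 (0.0589) or MSC replicate 2 (0.0869), and under other settings, up to 0.437 with thinned nuclei.

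Of 39 ribosomal protein genes 7 were lower and 0 higher in LSC (16 and 0 adjusted over the list alone), with Rpl19 at -0.85 ± 0.19 and a list median of -0.45 (camera adjusted p = 9.45e-12, and 0.320 with an estimated correlation). The number was 4, 3, 2 and 4 without LSC replicates 1, 2, 3 and 4, 3 without MSC replicate 1 or clusters 5 and 16, 2 with thinned nuclei and 4 with nuclei chosen by genes. With a length trend across genes removed the median went from -0.45 to -0.22. Of 49 potassium channel genes 8 were higher and 4 lower (11 and 7 adjusted over the list alone), among them Kcnmb2 (2.14 ± 0.12), Kcnma1 (1.26 ± 0.08) and Kcng4 (2.72 ± 0.39). Of 74 adhesion molecules 18 were higher and 10 lower (21 and 15 adjusted over the list alone), with Sdk1 at 1.21 ± 0.14 and Pcdh17 at -1.30 ± 0.12. Of 20 calcium-binding proteins 2 were higher and 3 lower (3 and 5 adjusted over the list alone), with Pvalb at 1.19 ± 0.13 and Calb2 at -1.53 ± 0.32. Of 22 monoamine and acetylcholine receptors 0 were higher and 3 lower (2 and 4 adjusted over the list alone), Drd2 and Chrm2 (-1.12 ± 0.20) among them. Ionotropic glutamate receptors split 2 and 2 of 18 (3 and 3), with Grin2a at 0.46 ± 0.08, and GABA and glycine receptors 1 and 2 of 18 (5 and 5 adjusted over the list alone), with Gabrg3 at 0.41 ± 0.08 and Gabrb1 at -0.48 ± 0.10.

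MSC nuclei were also higher in Ror1, Foxp2 and Six3 and lower in Pax5, a paired-box transcription factor (chromosome 4, 44524757 to 44710487). Ror1 was higher by 3.35 ± 0.22 on the log2 scale (edgeR adjusted p = 2.22e-12), Foxp2 by 2.70 ± 0.24 (4.39e-09), Six3 by 2.56 ± 0.33 (3.81e-06) and Six3os1 by 2.69 ± 0.41 (5.68e-05). Pax5 was at 36.6 ± 23.3 CPM in MSC (SD, n = 2) and 469 ± 43.1 in DR (n = 5; log2 -2.43 ± 0.36, adjusted p = 3.27e-05). The matrix protein gene Spon1 was at 21.1 ± 1.24 CPM in MSC and 190 ± 40.5 in DR (log2 -2.42 ± 0.27, adjusted p = 2.43e-07). The collagen gene Col24a1 was lower by a log2 of -3.01 ± 0.51 (0.000267). Myelin RNA was raised in 1 MSC plate: Mbp was at 77.7 CPM in MSC replicate 1 and averaged 23.2 to 30.6 in the other targets. Of 5 myelin genes 1 was higher and 0 lower in MSC (3 and 0 adjusted over the list alone), Mbp at 1.01 ± 0.26, and the camera adjusted p was 0.00494 (0.0791 with an estimated correlation). Without MSC replicate 1, Mbp was at 0.04 (adjusted p = 0.996) and the list at 0.221. With thinned nuclei the list was at 0.173.

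In MSC 279 genes passed (160 higher, 119 lower), 176 beyond 2-fold, and 143 without MSC replicate 1 (101 higher, 42 lower), of which 114 were among the 279. Several of the highest and lowest genes in MSC missed the test without 1 of its plates. Without MSC replicate 1 the test was missed by Uncx (3.12 ± 0.53, then 2.54, edgeR adjusted p = 0.207), Fxyd1 (3.02 ± 0.61, then 1.97, 0.687), Pax8 (-2.30 ± 0.45, then -1.73, 0.259), Pappa (-2.08 ± 0.45, then -1.41, 0.452) and Nmur2 (-1.78 ± 0.41, then -1.40, 0.454). The transcription factor Sox6 (2.67 ± 0.60) turned to -0.90 (0.928), and fell to 1.70 (0.293) with nuclei chosen by genes and to 1.33 (0.600) without the sub-cluster 2.3, which held myelin RNA. Without MSC replicate 2 it was missed by A2m (2.97 ± 0.64, then 2.24, 0.342), C1ql3, a secreted synaptic protein (2.96 ± 0.54, then 2.06, 0.219), and Hydin (-2.25 ± 0.44, then -1.78, 0.0919, and -3.47 without MSC replicate 1). Rbm7 (-2.37 ± 0.50) missed it without either plate (0.231 and 0.0555). With thinned nuclei Rbm7 (0.280), Pax8 (0.0755), Nmur2 (0.101) and Sox6 (0.0669) missed it too, and in DESeq2 C1ql3 (0.0723) and Sox6 (0.287).

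More adhesion molecules were lower than higher in MSC, 12 against 2 of 74 (19 and 4 adjusted over the list alone). Adgrl2 fell by 1.09 ± 0.16 on the log2 scale, and Tenm3 rose by 1.38 ± 0.13. The camera adjusted p was 0.0115, and 0.610 with an estimated correlation. The counts were 3 and 1 without MSC replicate 1 (0.565) and 8 and 1 without MSC replicate 2. Of 18 GABA and glycine receptors 1 was higher and 4 lower (2 and 5 adjusted over the list alone), with Gabrg3 at 0.81 ± 0.10 and Glra1 at -1.39 ± 0.23. That call (camera adjusted p = 0.0273, and 0.378 with an estimated correlation) ended without MSC replicate 1 (0.176) or 2 (0.0869, with 1 higher and 1 lower). Developmental transcription factors split into 14 higher and 8 lower of 65 (23 and 11 adjusted over the list alone), 9 and 4 without MSC replicate 1 and 8 and 6 without replicate 2. Axon guidance genes split into 4 and 4 of 54 (8 and 6), with Nrp1 at 1.27 ± 0.15 and Robo1 at -0.95 ± 0.13. Potassium channel genes split into 4 and 3 of 49 (9 and 3), 2 and 1 without MSC replicate 1, with Kcnt2 at -1.34 ± 0.20. Sodium, calcium and pacemaking channel genes split into 4 and 1 of 43 (6 and 1), 1 and 0 without MSC replicate 1. Grm3 (1.26 ± 0.14) was the 1 metabotropic receptor past the test and the serotonin receptor Htr2c (-1.15 ± 0.15) the 1 monoamine receptor. Calcium-binding proteins split into 2 and 1 of 20, ionotropic glutamate receptors into 1 and 2 of 18 and neuropeptide receptors into 1 and 0 of 20. Ribosomal protein genes held 0 calls in edgeR (4 at an unadjusted p under 0.05, 0 in DESeq2), with a median of 0.31 (camera adjusted p = 0.0187, and 0.733 with an estimated correlation), which was -0.18 (0.314) without MSC replicate 1 and missed the test with thinned nuclei (0.0929) and without sub-cluster 2.3 (0.0931) or 4 sub-clusters of cluster 10 (0.0550).

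In IC the largest differences included genes of transcription factors, of neuropeptides and of a synaptic vesicle protein. The AP-2 factor Tfap2b (chromosome 1, 19208914 to 19238576) was at 15.4 ± 2.40 CPM in IC (SD, n = 3), 0.653 in LSC and 0 in MSC (log2 5.59 ± 0.65, edgeR adjusted p = 1.39e-07). The peptide gene Cck (chromosome 9, 121489824 to 121495694) was at 41.3 ± 16.6 CPM in IC and at most 3.90 elsewhere (log2 4.17 ± 0.52, adjusted p = 4.17e-07). Arhgap6 was at 158 ± 28.1 CPM in IC and 4.87 in Med (log2 3.58 ± 0.25, adjusted p = 1.28e-12). Vipr2, a receptor for vasoactive intestinal peptide (4.47 ± 0.66), C1ql3 (4.37 ± 0.42) and the homeobox gene Emx2 (4.32 ± 0.60) were also among the 8 highest, with Otx2 (3.61 ± 0.72) and the parathyroid hormone receptor Pth2r (3.59 ± 0.58). Lower in IC was Synpr, a synaptic vesicle protein (chromosome 14, 13284780 to 13616340), at 25.5 ± 10.4 CPM against 417 ± 110 in PNo (n = 4; log2 -2.72 ± 0.25, adjusted p = 6.52e-10). The homeobox gene Irx5 had 1 count in IC and 384 elsewhere, a ratio of 50.2 with a counting interval of 8.95 to 1987. The receptor gene Acvr1c was at -3.03 ± 0.46, Fam163a at -3.15 ± 0.42 and Sox14 at -3.19 ± 0.63 (-5.24 without IC replicate 3).

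In IC 1051 genes passed (559 higher, 492 lower), 528 beyond 2-fold, with 687 without IC replicate 1 and 649 without IC replicate 3. Among the 8 lowest, Spp1 (-3.04 ± 0.71) missed the test without IC replicate 3 (-2.50, edgeR adjusted p = 0.0549) and with all nuclei (-1.95, 0.0548), Ddo (-2.78 ± 0.64) without IC replicate 1 (-2.16, 0.0579) and Fam20a (-2.85 ± 0.49) with thinned nuclei (-2.05, 0.0522). Pth2r missed it without IC replicate 3 (2.29, 0.0740) and without 4 sub-clusters of cluster 10 (1.80, 0.137), and Otx2 in DESeq2 (0.288).

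Of 9 neuropeptides, 3 were higher in IC and 0 lower (the same adjusted over the list alone), and 6 did not pass. Sst was at 114 ± 50.1 CPM in IC (log2 3.53 ± 0.62) and 42.4 ± 8.13 in MSC, and Nts at 7.36 ± 3.18 in IC and 0 in LSC and DR (log2 3.89 ± 0.84). Both missed the test in DESeq2 (adjusted p = 0.258 and 0.192). Counts of Cck were found in 106 of 239 IC nuclei, of Sst in 179 and of Nts in 22. The camera adjusted p of the list was 0.0146 (0.218 with an estimated correlation, 0.0981 without IC replicate 1, 0.0659 with nuclei chosen by genes). Neuropeptide receptors split into 3 higher and 2 lower of 20 (4 and 2 adjusted over the list alone; 1 and 1 without IC replicate 3, 1 and 2 with thinned nuclei), with Glp1r at 4.20 ± 0.68, Ntsr1 at 4.16 ± 0.65 and Hcrtr2 at -2.07 ± 0.25. More axon guidance genes were lower than higher, 14 against 6 of 54 (16 and 7 adjusted over the list alone), and 34 did not pass, with Rgma at -2.42 ± 0.37, Epha7 at -2.10 ± 0.18 and Sema3d at 3.20 ± 0.35. Their camera call (adjusted p = 0.0437, or adjusted p = 0.218 with an estimated correlation) ended without IC replicate 1 (0.0512) or 2 (0.124), LSC replicate 3 (0.0595), PNo replicate 1 (0.0574), 3 (0.0518) or 4 (0.0509), Med replicate 4 (0.0511) or MSC replicate 1 (0.0605), with thinned nuclei (0.0734) and with nuclei chosen by genes (0.0935).

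Developmental transcription factors went both ways in IC, 17 higher and 16 lower of 65 (21 and 21 adjusted over the list alone), with Nr2f2 at 3.55 ± 0.36. Adhesion molecules did so too, 18 and 16 of 74 (19 and 19 adjusted over the list alone), with the cadherin Cdh6 at 2.97 ± 0.16 (284 ± 67.3 CPM in IC, at most 49.9 elsewhere) and Cdh8 at -2.47 ± 0.17. Potassium channel genes split into 10 higher and 4 lower of 49 (15 and 6), with Kcnh8 at 2.83 ± 0.34 and Kcnh5 at 2.20 ± 0.17. Sodium, calcium and pacemaking channel genes split into 9 and 3 of 43 (11 and 3; 5 and 2 without IC replicate 1), led by the calcium channel subunit Cacna2d3 (2.89 ± 0.16). GABA and glycine receptors split into 4 and 6 of 18 (1 and 5 without IC replicate 3), with Glra1 at -1.81 ± 0.20. Ionotropic glutamate receptors split into 8 and 5 of 18, which was 6 and 1 without IC replicate 1, 8 and 0 without replicate 2 and 6 and 1 without replicate 3, with Grik3 at 1.58 ± 0.25. Calcium-binding proteins split into 4 and 5 of 20 (6 and 6), with Necab2 at 3.01 ± 0.42 and Kcnip4 at -1.79 ± 0.13. Metabotropic receptors split into 2 and 1 of 6, and monoamine and acetylcholine receptors into 3 and 2 of 22 (1 and 2 without IC replicate 1, 1 and 1 without replicate 3, 1 and 2 with thinned nuclei, 2 and 1 with nuclei chosen by genes), with Drd3 at 2.62 ± 0.55. Of 4 sex-linked genes 1 was higher, Uty at 0.38 ± 0.11. Its camera call (adjusted p = 0.0484, or adjusted p = 0.275 with an estimated correlation) ended under most settings tried, up to 0.153 with thinned nuclei, among them each IC plate left out (0.0971, 0.113 and 0.0686).

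**Figure D2:**
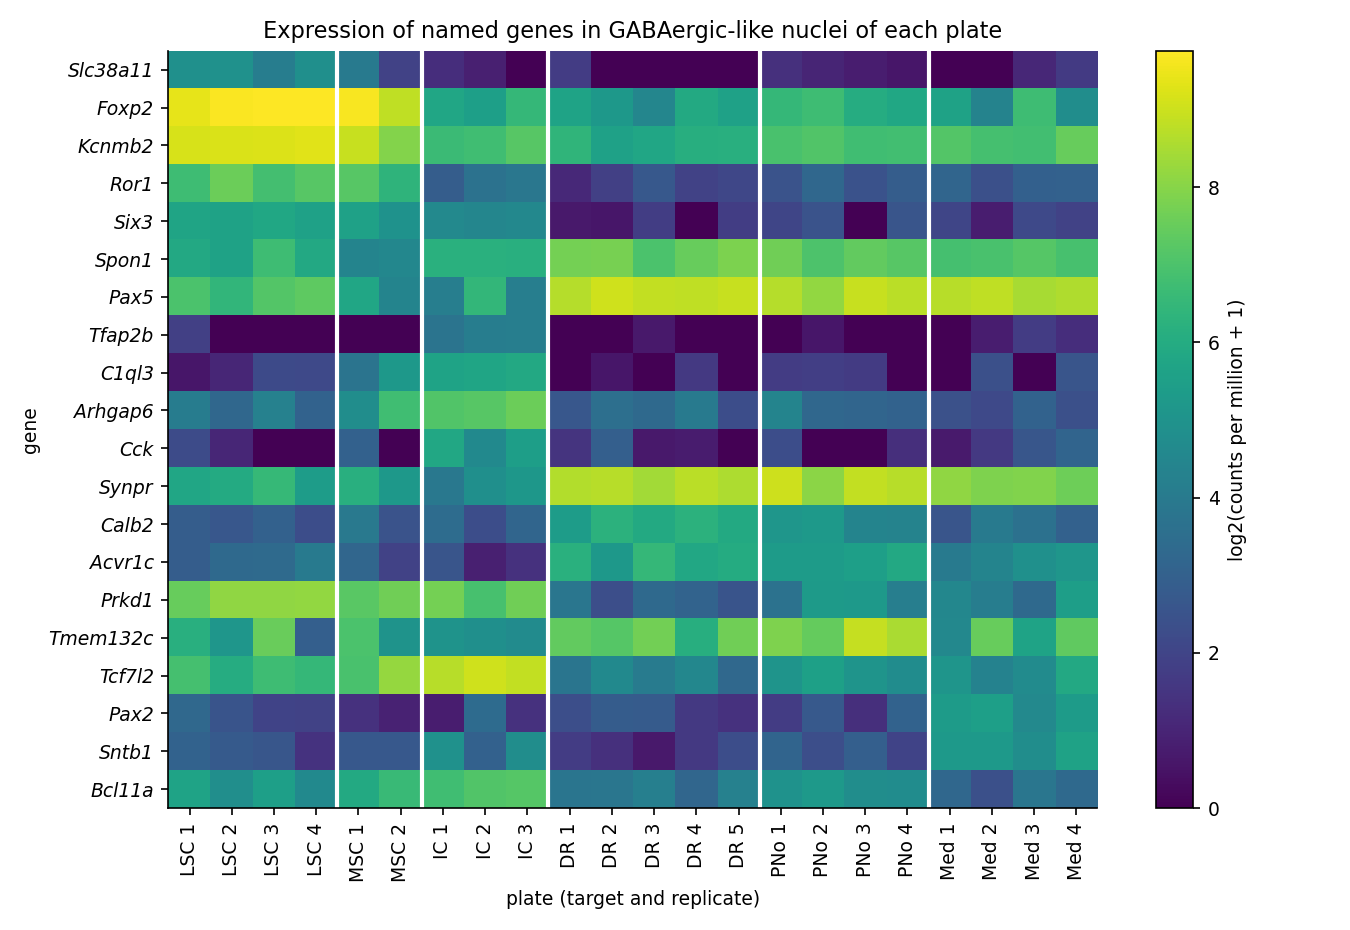
Heat map of log2(CPM + 1) of 20 genes (down the side) in GABAergic-like nuclei of each of the 22 plates (along the bottom, grouped by target). Tfap2b was at 15.4 ± 2.40 CPM in the 3 IC plates and Pax2 at 36.6 ± 9.38 in the 4 Med plates.

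DR nuclei were higher in calretinin and glycine receptor genes and lower in Six3 and Prkd1. Calb2, which encodes the calcium-binding protein calretinin (chromosome 8, 110137502 to 110168210), was at 62.9 ± 14.9 CPM in DR (SD, n = 5) and 5.70 in LSC (log2 2.62 ± 0.21, edgeR adjusted p = 5.15e-11). Acvr1c was at 63.5 ± 20.0 CPM (log2 2.50 ± 0.22, adjusted p = 2.44e-10) and Hydin at 52.8 ± 16.2 (2.04 ± 0.20, 3.87e-09). The kinase gene Prkd1 (chromosome 12, 50341231 to 50649098) was at 7.77 ± 3.71 CPM in DR and 256 ± 51.0 in LSC (n = 4; log2 -3.44 ± 0.30, adjusted p = 3.89e-10). Six3 was at 1.18 ± 1.13 CPM (log2 -3.45 ± 0.44, adjusted p = 7.93e-07) and Ano1 at 0.659 ± 0.580 (-4.57 ± 0.63, 3.08e-06). The other high genes were Cidea (2.69 ± 0.39), S100a10 (2.53 ± 0.41), Clrn1 (2.51 ± 0.44), Irs4 (2.25 ± 0.29) and Sytl5 (2.11 ± 0.24). The other low genes were Ctxn3 (-4.19 ± 0.51), Six3os1 (-4.14 ± 0.60), Emx2os, antisense to Emx2 (-3.74 ± 0.55), C1ql3 (-3.46 ± 0.75) and Ccdc192 (-3.37 ± 0.36). All 16 passed the test under every alternative tried. In DR 1338 genes passed (651 higher, 687 lower), 407 beyond 2-fold. With library size as the scaling 879 were higher and 500 lower. Without clusters 5 and 16, which held 281 nuclei with low totals (173 of the 440 DR nuclei were in cluster 16 and 90 of the 346 Med nuclei in cluster 5), 872 passed, of which 786 were among the 1338.

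More channel genes were lower than higher in DR. Of 49 potassium channel genes 18 were lower and 5 higher (20 and 7 adjusted over the list alone), with Kcnh8 at -2.32 ± 0.46 and Kcns2 at 3.32 ± 0.66 (camera adjusted p = 0.000599, and 0.0791 with an estimated correlation). Of 43 sodium, calcium and pacemaking channel genes 16 were lower and 4 higher (18 and 5), with Trpc7 at -2.22 ± 0.27, Cacna2d3 at -1.82 ± 0.19 and Scn4b at -1.62 ± 0.34 (0.000599, and 0.112 with an estimated correlation). Of 18 GABA and glycine receptors 8 were higher and 2 lower (8 and 3 adjusted over the list alone). The glycine receptor subunit Glra1 was at 223 ± 19.7 CPM in DR and 32.5 in IC (log2 1.53 ± 0.12), with Gabrg1 at 1.17 ± 0.15 and Gabra4 at 1.01 ± 0.16 (camera adjusted p = 0.0105, and 0.320 with an estimated correlation). Of 39 ribosomal protein genes 9 were higher and 0 lower (19 and 0 adjusted over the list alone), with Rpl3 at 0.80 ± 0.14 and a median of 0.46 (camera adjusted p = 2.33e-10, and 0.342 with an estimated correlation). The number was 3 without DR replicate 4, 3 without DR replicate 5, 15 without MSC replicate 1 and 4 without MSC replicate 2. Without clusters 5 and 16 it was 0, Rpl3 was at 0.47 (edgeR adjusted p = 0.0616) and the camera adjusted p was 0.00618. With a length trend across genes removed from log2 CPM the median difference went from 0.48 to 0.25.

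Developmental transcription factors split into 14 higher and 18 lower of 65 in DR (17 and 24 adjusted over the list alone), with Pax5 at 1.89 ± 0.18, Nr2f1 at -3.44 ± 0.66 and Gata2 at -3.29 ± 0.71. Axon guidance genes split into 11 and 13 of 54 (12 and 16), with Sema3f at 1.70 ± 0.33 and Ntng2 at -2.76 ± 0.56, and adhesion molecules into 11 and 17 of 74 (18 and 21), with Cdh8 at 1.23 ± 0.10. Calcium-binding proteins split into 7 and 4 of 20 (7 and 5), with Necab1 at 1.69 ± 0.15 and Pvalb at -1.42 ± 0.15. Ionotropic glutamate receptors split into 4 and 6 of 18 (4 and 6), with Grik4 at -0.89 ± 0.12 and Grin1 at -0.60 ± 0.11, and 2 of 6 metabotropic ones were lower. Monoamine and acetylcholine receptors split into 5 and 2 of 22 (6 and 3; 4 and 0 without DR replicate 4, 3 and 0 with thinned nuclei), with Htr2c at 1.17 ± 0.08 and Adra1a at 1.26 ± 0.24. Neuropeptide receptors split into 3 and 1 of 20 (3 and 2; 2 and 0 with thinned nuclei), with the tachykinin receptor Tacr1 at 1.32 ± 0.16 and Oprd1 at -1.74 ± 0.42, and neuropeptides into 1 and 1 of 9. The early gene Jund (1.32 ± 0.38, edgeR adjusted p = 0.0217) was the 1 of 8 past the test, and missed it without DR replicate 3 (0.0689) or 4 (0.0562). The mitochondrial mt-Cytb (0.92 ± 0.25, 0.0155) was the 1 of 6, and missed it without DR replicate 2 (0.119), with thinned nuclei (0.128) and without clusters 5 and 16 (0.0921). The sex-linked Uty (-0.39 ± 0.10, 0.00825) was the 1 of 4, and missed it with thinned nuclei (0.146) and without clusters 5 and 16 (0.111).

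PNo nuclei were higher in Synpr and Tmem132c and lower in Tcf7l2. Synpr was at 417 ± 110 CPM in PNo (SD, n = 4) and 62.0 ± 21.0 in LSC (n = 4; log2 2.13 ± 0.15, edgeR adjusted p = 3.64e-12). Tmem132c was at 312 ± 136 CPM (log2 2.02 ± 0.36, adjusted p = 0.000495), with its antisense Tmem132cos (2.10 ± 0.36), which cannot be told apart from it. Acvr1c (1.94 ± 0.24), Fam20a, a secretory-pathway kinase family member (1.95 ± 0.26), Hydin (1.78 ± 0.22) and Sytl5 (1.74 ± 0.27) were higher as well. Tcf7l2 was lower by a log2 of -1.37 ± 0.23 (adjusted p = 0.000244) and Ccdc192 by -1.85 ± 0.34 (-2.91 without PNo replicate 2). In PNo 323 genes passed (227 higher, 96 lower), 130 beyond 2-fold. The other named genes missed the test without single plates. These were Slc9a3 (1.72 ± 0.40) without PNo replicate 2 (adjusted p = 0.0634) and with all nuclei (0.0671), Six3os1 (-2.57 ± 0.57) without replicate 4 (0.0511), and Rorb (-2.09 ± 0.49) without replicate 3 (0.0696) or 4 (0.0502) and with thinned nuclei (0.0715). Six3 (-1.63 ± 0.40) missed it without PNo replicate 1 (0.0574) or 3 (0.0795) and without clusters 5 and 16 (0.0520). Nr2f2 (-2.19 ± 0.56) missed it without each PNo plate (0.0530 to 0.136), with thinned nuclei (0.253) and with nuclei chosen by genes (0.110). The peptide precursor gene Pnoc (-1.53 ± 0.40) missed it without PNo replicate 1, 2 or 4 (0.0961, 0.105 and 0.110), with all nuclei (0.0535) and with nuclei chosen by genes (0.0515), and Myo5b (-1.42 ± 0.35) without replicate 2, 3 or 4 (0.0804, 0.0773 and 0.0653), with all nuclei (0.0896) and with thinned nuclei (0.298).

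In PNo 12 of 74 adhesion molecules were higher and 4 lower (13 and 5 adjusted over the list alone), 7 and 3 without PNo replicate 4, with Cdh8 at 1.12 ± 0.11, Cdh9 at 0.98 ± 0.12 and Kirrel3 at 0.79 ± 0.11. Axon guidance genes split into 7 higher and 3 lower of 54 (11 and 7), with the ephrin receptor Epha3 at 1.26 ± 0.17 and Slit3 at 1.10 ± 0.12. Developmental transcription factors split into 9 and 10 of 65 (19 and 16 adjusted over the list alone), with Pax5 at 1.63 ± 0.19. Monoamine and acetylcholine receptors held 4 higher and 0 lower of 22 (6 and 0; 2 and 0 without PNo replicate 4), with Drd2 at 1.15 ± 0.24 and Htr2c at 0.90 ± 0.09. GABA and glycine receptors split into 3 and 1 of 18 (4 and 1), with Glra1 at 1.31 ± 0.13 and Gabrb1 at 0.55 ± 0.09. Potassium channel genes split into 4 and 3 of 49 (4 and 7), with Kcnma1 at -0.63 ± 0.09, and sodium, calcium and pacemaking channel genes into 2 and 5 of 43 (3 and 6), with Cacna2d3 at -1.11 ± 0.19. The latter were 2 and 2, 1 and 3 and 1 and 3 without PNo replicates 1, 3 and 4, and 2 and 2 with thinned nuclei. Calcium-binding proteins split into 3 and 0 of 20 (4 and 2), with Necab1 at 1.05 ± 0.17. Ionotropic and metabotropic glutamate receptors split into 1 and 1 each, neuropeptides into 0 and 1 of 9 (2 and 1) and neuropeptide receptors into 1 and 0 of 20. Of 7 dopamine neuron genes Drd2 alone was higher (4 and 0 adjusted over the list alone). Camera gave that list an adjusted p = 0.0115, which was 0.218 with an estimated correlation and 0.0631 without PNo replicate 4. Ribosomal protein genes held 0 higher and 1 lower of 39 (0 and 2 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.000296, and 0.610 with an estimated correlation). Their call ended without PNo replicate 3 (0.0518) or 4 (0.0707).

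Med nuclei were higher in the paired-box factors Pax2 and Pax8 and in a nicotinic receptor subunit. Pax2 (chromosome 19, 44756045 to 44837871) was at 36.6 ± 9.38 CPM in Med (SD, n = 4) and at most 4.85 elsewhere (log2 3.38 ± 0.35, edgeR adjusted p = 2.44e-08). The syntrophin Sntb1 was at 37.7 ± 8.97 CPM (log2 2.70 ± 0.28, adjusted p = 4.06e-08), the growth factor Hgf at 30.4 ± 3.89 (2.41 ± 0.29, 5.11e-07) and the nicotinic subunit Chrnb3 at 11.1 ± 2.56 (2.80 ± 0.54, 0.000867). Kcns3, a modulatory potassium channel subunit (2.76 ± 0.37), Spp1, which encodes osteopontin (2.28 ± 0.36), Atp10b (2.20 ± 0.39, and 3.37 without MSC replicate 1) and Pax8 (2.10 ± 0.22) were higher too. Bcl11a, a transcription factor, was at 8.78 ± 3.66 CPM in Med and 130 ± 20.6 in IC (n = 3; log2 -2.27 ± 0.26, adjusted p = 1.6e-07). Arhgap6 (-2.39 ± 0.38), Sox2ot (-2.37 ± 0.33) and Cadps2 (-2.21 ± 0.35) were lower, and the calcium-binding protein gene Necab2 had 3 counts in Med and 355 elsewhere (ratio 25.7, counting interval 8.71 to 125). In Med 479 genes passed (272 higher, 207 lower), 206 beyond 2-fold. Qrfprl (2.43 ± 0.60) missed the test without Med replicate 4 (1.82, adjusted p = 0.247) and in DESeq2 (0.141). Wls (-2.21 ± 0.56) missed it without Med replicate 2 (0.0909) or 3 (0.0805) and with thinned nuclei (0.0579), Emx2os (-2.70 ± 0.55) with thinned nuclei (0.170), and Gulp1 (-2.61 ± 0.58) with thinned nuclei (0.0817) and with all nuclei (0.244).

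In Med 11 of 74 adhesion molecules were higher and 6 lower (17 and 9 adjusted over the list alone), with Cdh4 at 1.50 ± 0.14 and the teneurins Tenm2 at -1.44 ± 0.11 and Tenm3 at -1.28 ± 0.12. Axon guidance genes split into 3 higher and 7 lower of 54 (7 and 11), with the netrin receptor Unc5d at 1.32 ± 0.13 and Nrp1 at -1.34 ± 0.14. Developmental transcription factors split into 11 and 8 of 65 (14 and 16 adjusted over the list alone). Monoamine and acetylcholine receptors held 4 higher and 0 lower of 22 (4 and 0), with Adra1a at 1.34 ± 0.26 and Chrm3 at 0.93 ± 0.12, and neuropeptide receptors 4 and 0 of 20 (4 and 3; 2 and 0 with thinned nuclei), with Tacr1 at 1.31 ± 0.17. GABA and glycine receptors split into 4 and 1 of 18 (7 and 2; 7 and 1 without 4 sub-clusters of cluster 10), with Glra1 at 0.74 ± 0.14 and Gabrg3 at -0.62 ± 0.09. Potassium channel genes split into 5 and 5 of 49 (8 and 7; 3 and 2 without Med replicate 1), with Kcnh5 at -0.96 ± 0.20, and sodium, calcium and pacemaking channel genes into 0 and 4 of 43 (3 and 7; 2 and 6 without clusters 5 and 16), with Trpc4 at -1.26 ± 0.15. Calcium-binding proteins split into 3 and 2 of 20 (4 and 4), with Pvalb at 0.76 ± 0.14, and ionotropic glutamate receptors into 3 and 0 of 18. Of 6 metabotropic glutamate receptors 2 were lower and 0 higher (4 and 0 adjusted over the list alone), with Grm8 at -0.88 ± 0.17. Camera gave them an adjusted p = 0.0269, which was 0.320 with an estimated correlation, 0.0931 without Med replicate 3 and 0.0563 without Med replicate 4.

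**Figure D3:**
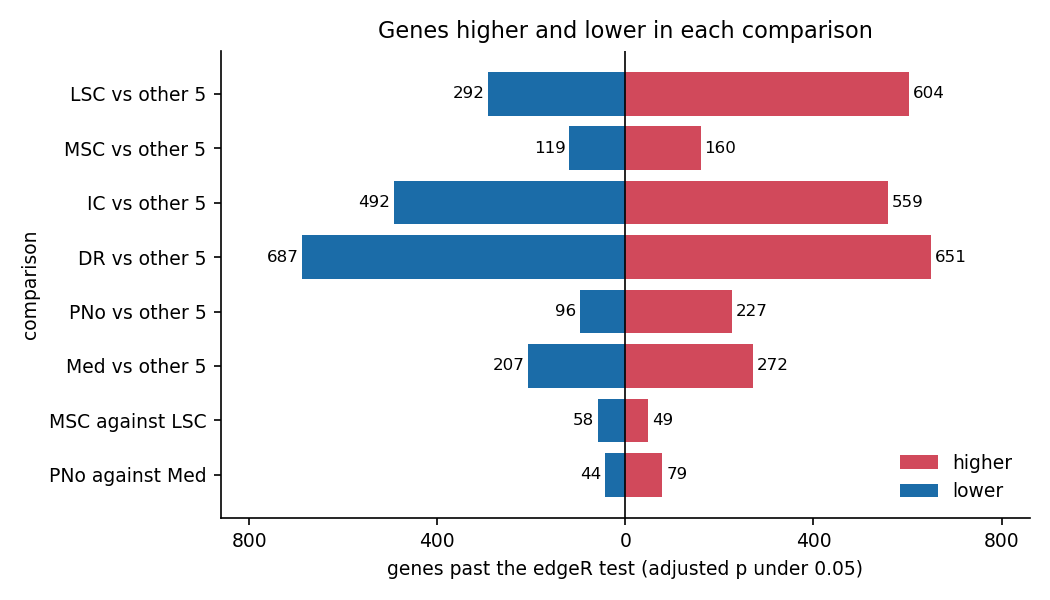
Number of genes past the edgeR test (horizontal axis) in each of the 8 comparisons (vertical axis), with bars for genes higher to the right and lower to the left. DR had 651 higher and 687 lower, and MSC against LSC 49 higher and 58 lower.

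Across the lists, 21 of 138 camera tests passed with the preset correlation and 0 with an estimated one. At an unadjusted p under 0.05 the numbers were 34 and 20, the smallest adjusted p with an estimated correlation was 0.0791, and fry called 26 lists, 17 of the 21 among them. Where a list held 0 calls in edgeR it also held 0 in DESeq2. GABA synthesis and transport genes held 0 in every target (8 tested). At an unadjusted p under 0.05 these were 3 in LSC, 2 in Med, 0 in MSC and 1 in each of the others, and 3 were higher in LSC adjusted over the list alone. Astrocyte genes (7 tested) held 0 calls, and 2 in LSC, 2 in MSC, 1 in DR and 3 in PNo at an unadjusted p. Interferon response genes (6 tested) held 0 as well, and 3 in MSC, 1 in IC and 2 in Med at an unadjusted p, with 2 higher in MSC and 2 in Med adjusted over the list alone. The 1 tested glutamate neuron gene, Slc17a6, passed in none (edgeR unadjusted p under 0.05 in LSC and IC). Neuropeptides held 0 calls in MSC (4 at an unadjusted p, 2 higher adjusted over the list alone) and in Med (3, with 2 lower), and ribosomal protein genes 0 in IC (5) and Med (2). Myelin, immediate early, mitochondrial and sex-linked genes held no calls beyond those given here, and at an unadjusted p 4 myelin genes in MSC and 3 sex-linked genes in Med, which were lower adjusted over the list alone, were the most. Of 4 microglia genes 0 were higher and 1 lower in LSC (0 without LSC replicate 2 or 3), and 0 passed in MSC, IC, DR, PNo and Med (2, 0, 2, 1 and 0 at an unadjusted p). Of the dopamine neuron genes, Ddc was higher in IC (1.97 ± 0.43, but adjusted p = 0.0614 without IC replicate 3), and Aldh1a1 lower in Med (-2.49 ± 0.61, but 0.0585 without Med replicate 2 and 0.0624 without Med replicate 4). Hox genes were below the count filter.

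**Figure D4:**
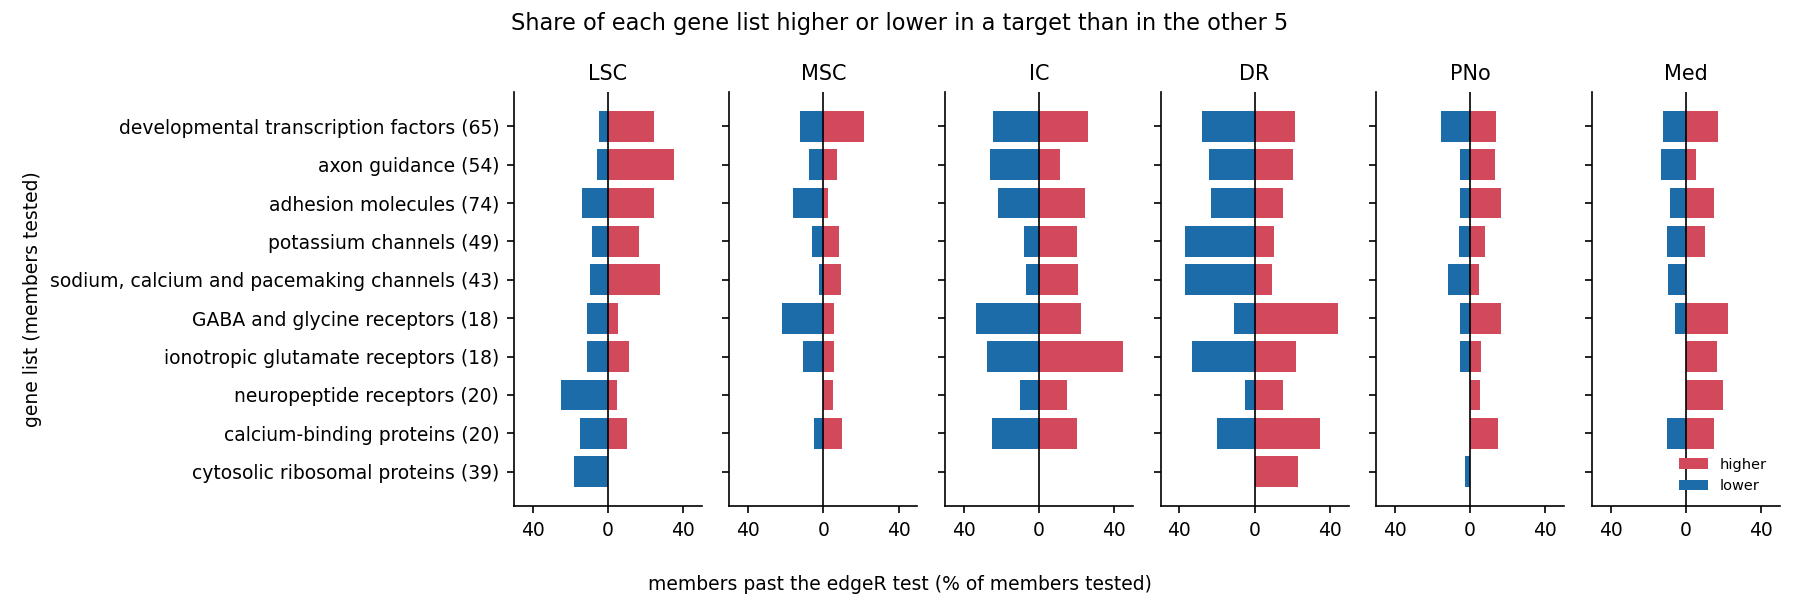
Percent of tested members of 10 gene lists that were higher or lower (bars, horizontal axis) in each target than in the mean of the other 5, with the number tested in brackets. Of 54 axon guidance genes 19 were higher and 3 lower in LSC.

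MSC against LSC asked whether this pair of targets differed. Pcsk5, a proprotein convertase (chromosome 19, 17432319 to 17837632), was at 40.2 ± 1.15 CPM in MSC (SD, n = 2) and 143 ± 29.4 in LSC (n = 4; log2 -1.82 ± 0.26, edgeR adjusted p = 0.000142). It passed under every alternative tried. Ptma was at 11.7 ± 3.58 CPM in MSC and 0.633 ± 0.597 in LSC (log2 4.16 ± 0.84, adjusted p = 0.00769), but missed the test without MSC replicate 1 (3.78, 0.140). Cntnap3 (-2.21 ± 0.42, 0.00497) missed it without MSC replicate 2 (-1.88, 0.104). C1ql3 (3.47 ± 0.74) missed it without MSC replicate 2 (0.234) or LSC replicate 2 (0.0506), with nuclei chosen by genes (0.0897) and in DESeq2 (0.0997). Fxyd1 (4.02 ± 0.92), the chaperone Cryab (3.16 ± 0.77) and the cyclin Ccnd2 (2.97 ± 0.68) were higher, and Col24a1 (-2.67 ± 0.55), Rbm7 (-2.34 ± 0.54) and the synaptotagmin Syt6 (-1.85 ± 0.42) lower. Fxyd1 and Cryab were at 22.4 and 44.3 CPM in MSC replicate 1, the plate with raised Mbp, and at 7.33 and 20.2 in MSC replicate 2, and astrocyte genes had a median of 1.43 in MSC against the other 5 targets (camera adjusted p = 0.0754, unadjusted 0.0126). Fxyd1, Cryab, Ccnd2, Col24a1, Rbm7 and Syt6 missed the test without MSC replicate 1, at adjusted p = 0.506, 0.462, 0.0956, 0.119, 0.316 and 0.0610. They also missed it without LSC replicate 1 (Fxyd1 0.0582, Cryab 0.0814), LSC replicate 2 (Fxyd1 0.0869, Cryab 0.0903, Ccnd2 0.0882), LSC replicate 3 (Fxyd1 0.0790, Syt6 0.0690), LSC replicate 4 (Cryab 0.0807, Ccnd2 0.0536, Rbm7 0.0717) or MSC replicate 2 (Ccnd2 0.0996, Col24a1 0.0921, Rbm7 0.109, Syt6 0.234). In all 107 genes passed (49 higher, 58 lower), 67 beyond 2-fold. Left out, MSC replicate 1 left 77 (45 and 32), MSC replicate 2 left 86 (62 and 24) and LSC replicate 3 left 69. With library size as the scaling 86 were higher and 36 lower, and the median of all genes was 0.117 above 0.

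PNo against Med compared another pair. Prkg1, a cGMP-dependent kinase (chromosome 19, 30564489 to 31765033), was at 649 ± 153 CPM in PNo (SD, n = 4) and 180 ± 41.7 in Med (n = 4; log2 1.85 ± 0.16, edgeR adjusted p = 8.75e-09). The prolactin receptor Prlr was at 60.3 ± 6.42 CPM in PNo and 16.4 ± 2.43 in Med (log2 1.87 ± 0.31, adjusted p = 0.000354). Bcl11a (1.74 ± 0.30) and Egfem1 (1.54 ± 0.16) were higher in PNo as well. Pax2 (-3.02 ± 0.50), Sntb1 (-2.85 ± 0.43) and D7Ertd443e (-2.17 ± 0.37) were lower in PNo. Mal2 (2.09 ± 0.41) missed the test with thinned nuclei (1.92, 0.0743). Spp1 (-2.21 ± 0.49) missed it without PNo replicate 1 (0.0622), 3 (0.0547) or 4 (0.0724) and in DESeq2 (0.0614). Kcns3 (-2.25 ± 0.52) missed it without PNo replicate 1 (0.0719), 2 (0.0586) or 3 (0.0827), Med replicate 1 (0.0892), 2 (0.0624) or 4 (0.0887), with all nuclei (0.107) and with thinned nuclei (0.0892). In all 123 genes passed (79 higher, 44 lower), 60 beyond 2-fold, with 80 without PNo replicate 1 and 76 without Med replicate 2.

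Shares of nuclei with a count asked how the 12 genes fixed in advance were spread over nuclei. After thinning, Pax5 was found in 94.4 ± 2.18% of DR nuclei (SD, n = 5), 85.6 ± 3.26% in PNo (n = 4) and 89.3 ± 3.30% in Med (n = 4), against 37.9 ± 4.23% in LSC (n = 4), 15.2 ± 12.1% in MSC (n = 2) and 13.2 ± 8.84% in IC (n = 3). Six3 was found in 29.9 ± 3.19% of LSC, 26.0 ± 3.70% of MSC and 14.4 ± 0.664% of IC nuclei, and in at most 2.80 ± 1.52% elsewhere. Foxp1 ran from 47.9 ± 4.22% in Med to 82.3 ± 3.80% in LSC. Each of these 3 differed across targets at p = 1e-05, the smallest that the permutation test can give (adjusted p = 3e-05). Parvalbumin (Pvalb) was found in 53.7 ± 14.5% of LSC and 16.6 ± 2.68% of DR nuclei (permutation test, adjusted p = 7e-05), and the LSC plates spread widely. Otx2 was found in 11.1 ± 2.46% of IC nuclei and at most 4.17 ± 5.89% elsewhere (0.0037). Zfpm2 (0.00072), Npas1 (0.00288), Sox14 (0.00671) and Tal1 (0.0196) differed too, Tal1 not without Med replicate 1 (0.0530) or without thinning (0.130), and Npas1, Sox14 and Tal1 not when 2 counts were required (0.255, 0.0784 and 0.191). Calb1 (0.182) and Nkx6-2 (0.628, 3 nuclei) did not, although Calb1 passed without PNo replicate 2 (0.0218) and when 2 counts were required (0.0218). Of the 72 tests of 1 target against all other plates, 5 passed (exact permutation test), among them Six3 and Foxp1 in LSC, Otx2 in IC (adjusted p = 0.0117 each) and Pax5 in IC (0.0374).

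**Figure D5:**
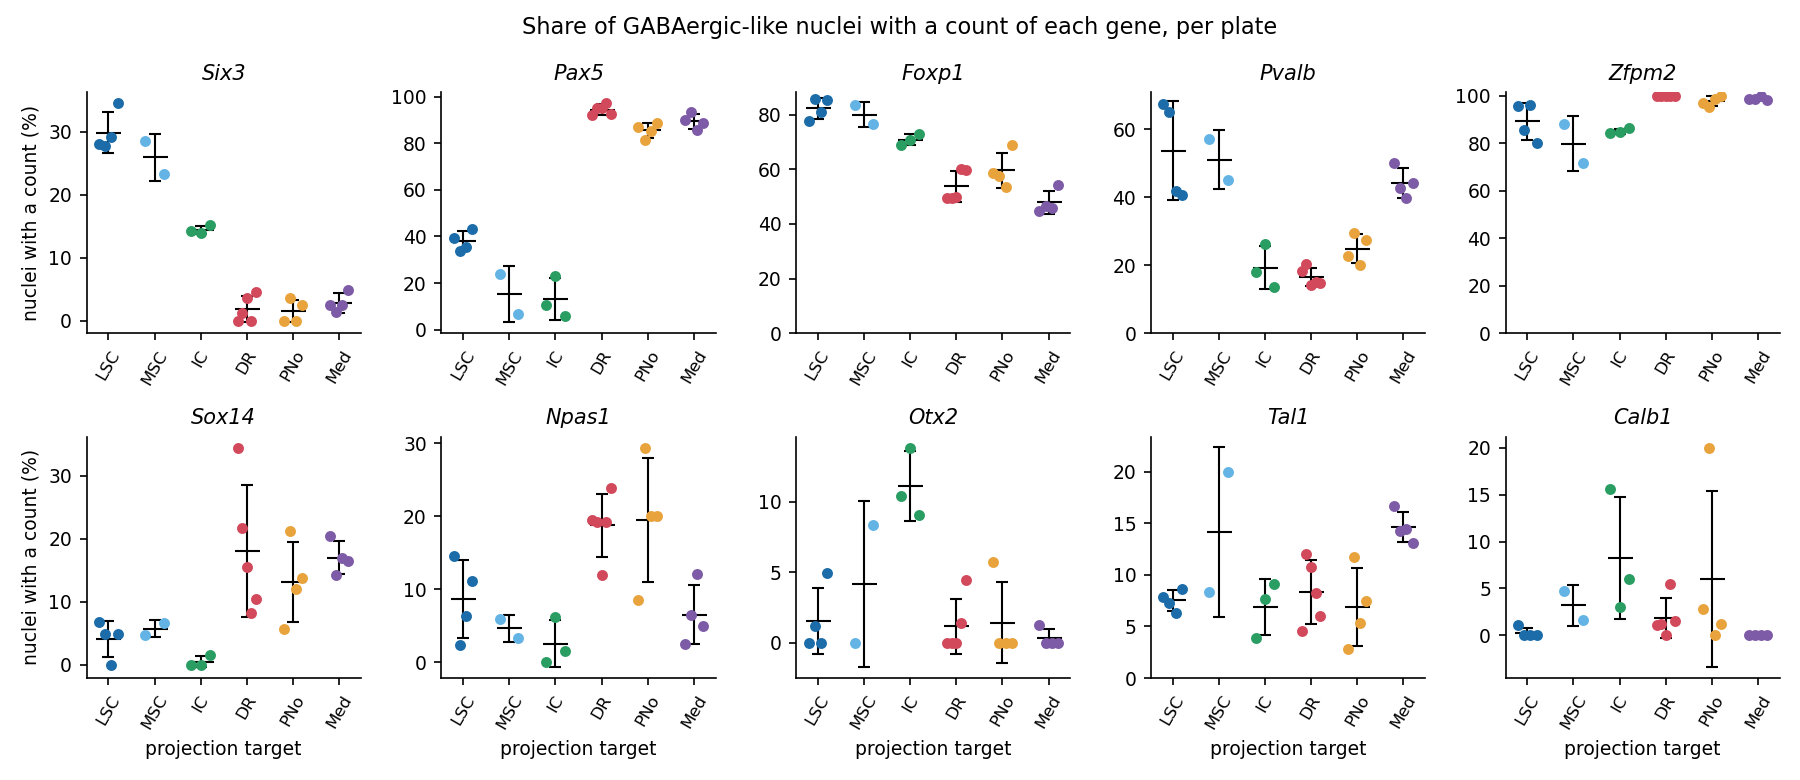
Percent of GABAergic-like nuclei with a count (vertical axis) for 10 of the 12 genes after thinning, 1 point per plate, with mean ± SD per target. Pax5 was at 94.4 ± 2.18% in DR and 13.2 ± 8.84% in IC.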

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

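Plates that stood far from the others of their target were sought in 69 sets of plates, each a depth or a share in 1 target with 4 or 5 plates. Chance gives such a plate in about 1 in 20 sets, and 12 were found. In 8 of the 12 the other plates were all at 0%, so that a single nucleus was enough. The share of Slc17a6 in the unnamed nuclei was looked at only after the classes had been seen.

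LSC replicate 3 had a share of GABAergic-like nuclei of 88.5%, against 93.8 to 94.8% on the other 3 LSC plates, and a share of unnamed nuclei of 11.5%, against 5.21 to 6.25%. Dopaminergic-like nuclei were 1.04% of LSC replicate 1 and 1.04% of Med replicate 2, and 0 on the other plates of both targets. Oligodendrocyte-like nuclei were 1.04% of DR replicate 5 and 0 on the other 4 DR plates.

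Among the genes fixed in advance, Otx2 was found in 5.71% of nuclei of PNo replicate 1 and 1.28% of Med replicate 1, and in 0 on the other plates of both targets. Nkx6-2 was found in 1.27% of nuclei of LSC replicate 3 and 1.18% of PNo replicate 2, and in 0 on their companions. Calb1 was found in 1.12% of nuclei of LSC replicate 1 (0 on the other 3 plates), 5.48% of DR replicate 4 (0 to 1.49% on the other 4) and 20.0% of PNo replicate 2 (0 to 2.86% on the other 3).

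The unnamed nuclei were left out of the comparisons of targets, except under the alternative with all nuclei. Slc17a6, a vesicular glutamate transporter, was found in 62.6% of them after thinning (122 of 195). In GABAergic-like nuclei it was found in 5.28% (89 of 1687). Median totals were 16083 and 17760.5 counts. The naming rule sets Gad1 and Gad2 against Slc17a6, so this difference follows at least in part from the rule.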

How the results depend on the processing

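The alternatives without clusters 5 and 16, without 4 sub-clusters of cluster 10 and without sub-cluster 2.3 were chosen after seeing the data. Counts of genes stayed within 1.5 times of the reported ones under relative log expression scaling, library size alone, all nuclei, at least 2000 genes per nucleus, no nucleus filter, without very high totals, nuclei chosen by genes, thinned nuclei, and without 4 sub-clusters of cluster 10 or sub-cluster 2.3. Of 380 pairs of a named gene and a comparison past the test, 233 kept the call under all 36 alternatives, 147 lost it under at least 1 and 124 on leaving out a plate. Thinned nuclei ended 55 of these calls, leaving out MSC replicate 1 ended 50, MSC replicate 2 30, all nuclei 29, the replicate block 29, clusters 5 and 16 28 and nuclei chosen by genes 26. DESeq2 ended 16, library size alone 4, no gene filter 2 and relative log expression 1. Of 61 pairs not past the test, 10 passed under some alternative. Except where named, the cause was not tested.

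With no gene filter more genes were tested, and 471 passed in MSC, 523 in PNo, 293 in MSC against LSC and 260 in PNo against Med. DESeq2 gave 176 in MSC against LSC and 185 in PNo against Med. Without clusters 5 and 16, which removed 281 nuclei, 872 passed in DR. With an estimated correlation 0 gene list tests passed camera (20 at an unadjusted p under 0.05, 26 by fry). Shares of nuclei with at least 2 counts had a range across targets of 4.20 points for Sox14, 2.62 for Tal1 and 3.73 for Npas1, which missed the test, and 2.32 for Calb1, which passed it (adjusted p = 0.0218). Without thinning Tal1 had 11.9 points and missed it.

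Class shares passed the permutation test at a Leiden resolution of 0.5, with ranges across targets of 9.55 points (GABAergic), 1.74 (dopaminergic), 5.21 (oligodendrocyte-like) and 9.38 (unnamed), and at 2000 genes per nucleus with 16.3 (GABAergic) and 15.5 (unnamed). Their ranges were 9.72, 1.74, 1.56 and 8.25 as reported.

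On leaving out 1 plate, the F test called 1831 to 2217 genes, LSC 589 to 948, MSC 143 to 312, IC 649 to 1128, DR 1008 to 1459, PNo 220 to 334, Med 343 to 499, MSC against LSC 69 to 159 and PNo against Med 76 to 141. The lowest counts came without LSC replicate 3 (F test, LSC, MSC against LSC), MSC replicate 1, IC replicate 3, DR replicate 2, PNo replicate 3, Med replicate 1 and Med replicate 2. Ranges of shares ran from 26.8 to 29.1 points for Six3, 79.2 to 87.8 for Pax5, 33.4 to 36.5 for Foxp1, 34.4 to 41.5 for Pvalb, 14.9 to 28.3 for Zfpm2, 16.5 to 20.0 for Sox14, 7.30 to 13.1 for Tal1, 15.7 to 20.6 for Npas1, 9.42 to 11.8 for Otx2, 0.316 to 0.649 for Nkx6-2 and 6.03 to 10.8 for Calb1. Class shares ran from 7.81 to 15.6 (GABAergic), 1.04 to 2.60 (dopaminergic), 1.30 to 3.13 (oligodendrocyte-like) and 6.51 to 15.9 (unnamed). Sox6 in MSC reversed to -0.90 without MSC replicate 1, which held the myelin RNA, against 3.57 without MSC replicate 2, and Npsr1 in MSC (2.47 ± 0.59) fell to -0.0610 without MSC replicate 2, against 3.37 without MSC replicate 1. A lone MSC plate is assumed to vary like the other groups.

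Plates of different targets share replicate numbers, and nothing in the labels ties them. Of 46 pairs of plates with the same number 0 had deviations correlated above 0.1, and 5 of 22 plates correlated best with a plate of their own number. With the replicate block MSC against LSC had 70 calls, the other 8 counts stayed within 1.5 times, and 16 gene lists passed camera, 15 of the 21 among them. It ended the calls of developmental transcription factors and neuropeptides in LSC, of adhesion molecules, GABA and glycine receptors and ribosomal proteins in MSC and of sex-linked genes in IC.

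A gene at 0 in IC can be bounded only from 3 counts over 4044357, which for Kcnj5 is at least 7.32-fold lower than in the other targets. On simulated plates 63% of genes changed 2-fold were recovered in the LSC comparison, the only one simulated.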

Other observations

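The tests on mitochondrial transcripts and on Foxp2 within plates, and the genes named in unnamed nuclei, were chosen after the results they bear on had been seen. The nuclei left unnamed differed from the GABAergic-like ones in the shares with a count of several genes, pooled over plates and not tested. After thinning, Cacna2d1, a calcium channel subunit, was found in 98.5% of 195 unnamed nuclei and 29.9% of 1687 GABAergic-like ones, and Ntng1, a netrin-like adhesion protein, in 77.4% and 37.3%. Foxp2 was found in 72.3% and 43.5%, the transcription factor Ebf2 in 31.3% and 5.22%, and Meis2 in 15.4% and 4.80%. Gad1 was found in 44.1% and 79.0%, Gad2 in 41.5% and 80.1% and Pax5 in 37.9% and 64.1%. The naming rule uses Gad1 and Gad2, so their lower shares follow at least in part from it. All 9 thinned dopaminergic-like nuclei had a count of Slc6a3, the dopamine transporter, and 8 had Foxp2. Of 8 thinned oligodendrocyte-like nuclei 6 had Gad1 and 7 had Gad2.

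Clusters of GABAergic-like nuclei differed in how they drew on the targets. Of LSC nuclei 240 of 356 fell in 1 cluster, and of IC nuclei 153 of 239. DR, PNo and Med each had a different largest cluster, with 173 of 440, 118 of 338 and 110 of 346 nuclei. That of DR was cluster 16, of low totals (median 11356 counts) with metabolic genes leading, so it may reflect depth or quality. Of 163 MSC nuclei 31 fell in the cluster that held 153 IC nuclei. Sub-clusters 2.0, 2.1, 2.3 and 2.4 held 26, 24, 24 and 13 MSC nuclei. These were split from 1 first-round cluster and together held more MSC nuclei than any other, so MSC was not spread more widely on these counts.

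Shuffled targets were used to ask how often chance labels give as many calls. The F test called 2068 genes with the real targets and at most 195 in the other splits. LSC had 896 against at most 626, IC 1051 against 3, DR 1338 against 56, PNo 323 against 35 and Med 479 against 1, in 100 splits each with the real one. PNo against Med had 123 against at most 11 in all 35 splits. The real split alone reached its count in each of these 7 (1 of 100, or 1 of 35), the smallest share that so many splits can give. Chance labels are therefore an unlikely source of these counts, but are not excluded. Shuffled plates do not separate a target from the preparations made for it. The comparisons of MSC, with 2 plates, were not shuffled.

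Of 39 ribosomal protein genes 9 were higher in DR, with a list median of 0.46 and a camera adjusted p of 0.342 with an estimated correlation. The median was 0.40 with every nucleus thinned to the same total. Thinning leaves the expected proportions within a nucleus unchanged, so it cannot decide whether the list goes with low totals. The median was 0.22 with 0 calls without clusters 5 and 16, of low totals, which held 173 of 440 DR nuclei in cluster 16 alone. Gene length may account for part of it: across 12525 genes log2 changes in DR fell with length (Spearman rho -0.290 across genes, which are not independent), and the median was 0.25 once the trend was removed. Cytoplasmic RNA carried along with nuclei stays open, since mitochondrial transcripts averaged 0.34 ± 0.15 (SE) in DR, within their error of the list. These and a difference between the neurons cannot be told apart.

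Pax5 and Zfpm2 were higher in DR, PNo and Med, and Foxp1 lower. Six3 was higher in LSC, MSC and IC (log2 1.61 in IC) and Foxp2 in LSC and MSC. In IC Pax5 (-2.37) and Zfpm2 (-0.80) were lower. Nuclei of other classes are argued against, since the called changes recomputed with nuclei chosen by Gad1, Gad2 and Slc32a1 (for Foxp2 those in LSC and MSC only) kept at least 0.861 of their log2 value. A shift of whole plates was expected to leave no relation between nuclei of 1 plate. Such a relation can exist with or without a shift, so the test cannot decide on it. It covered 9 plates with at least 10 nuclei on each side, with no DR plate among them. On 8 of 9 plates Foxp2 was lower in nuclei with a Pax5 count (mean log2 ratio -0.84 ± 0.38 SE). IC replicate 2 went the other way (1.08). Zfpm2 was higher in nuclei with Pax5 on 8 of 9 plates (0.79 ± 0.15). Six3 (0.06 ± 0.19) and Foxp1 (-0.29 ± 0.27) lay within 2 standard errors of 0. The pattern may hold between nuclei as well as between targets for Zfpm2, and a target is not separable from its preparations.

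Cck, Sst and Nts were higher in IC. The 4 GABAergic-like sub-clusters of cluster 10 are argued against as the source, since the median of the 3 log2 changes was 4.09 without them. They were split from a cluster with Slc17a6 nuclei. Slc17a6 was detected in 16.7%, 33.3%, 50.0% and 0% of nuclei in sub-clusters 10.1, 10.3, 10.4 and 10.6. RNA from the unnamed Slc17a6 nuclei is argued against for Sst. Such RNA could give 26.5 CPM of Cck, 15.7 of Sst and 2.79 of Nts, against 40.8, 110 and 7.17 measured in IC. The lower 95% counting bounds of the measured levels were 34.8, 99.6 and 4.80. The counting error of the levels that such RNA could give was left out. Those levels rest on 133 Cck and 14 Nts counts in unnamed nuclei, so Cck and Nts stay undecided. A hypothesis is that some GABA neurons projecting to IC express these peptides, which DESeq2 did not call for Sst and Nts (adjusted p = 0.258 and 0.192).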
